A study of Mus musculus with 2 samples.

How the data were processed

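MicroRNA sequencing was available for embryonic mouse heart at day 11.5 in 2 libraries, which the labels give as biological replicates 1 and 2 of 1 group. The labels put the RNA at sizes under 30 nt and name pooled male and female embryos; replicate 1 pooled hearts of 109 embryos, and the number for replicate 2 is not given in the sources used here. The labels name separate tissue samples for the replicates, with no word on litters.

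The authors deposited raw read counts per miRNA gene, on genome build mm10 with the GENCODE M4 annotation, per the file headers of the accompanying notes. The aligner and the counting tool are not given in the sources used here. Each table has 3 unlabelled count columns and 4 summary rows for reads on no gene. From their layout and sums, the columns were taken as reads on both strands, on the gene's own strand and on the opposite strand; no source used here states this. The last 2 columns added up to the first for every gene. The own-strand counts were used as the main values. The summary rows were left out of library sizes and tests. They held 38.4% unmapped, 20.8% multimapping and 8.77% reads on no gene's own strand in replicate 1, against 27.5%, 24.1% and 7.04% in replicate 2. The last of these shares takes in the opposite-strand reads on genes. Ambiguous reads numbered 0 in both. By the layout of the counts, a read that maps to several places stands in the multimapping row and on no gene. Genes whose mature sequence occurs at several loci, taken from symbols ending in a hyphen and 1 digit, were therefore named as uncertain. Mir467a-10, with 2 digits, was left among the single-locus genes. A rule by symbol can also miss genes of other names that share sequence. Mir23a, at 21645 CPM, shares some runs of 20 bases (20-mers) with another annotated hairpin and is not marked.

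The table holds 1973 genes. By gene ID, 1894 matched GENCODE M21 on GRCm38, the same build, all of type miRNA, and 1815 had the same ID version; the 79 unmatched genes held 6 own-strand counts in replicate 1 and 2 in replicate 2. Symbols, coordinates (1-based) and overlapping host genes on the same strand came from M21. A host exon means an exon of any annotated transcript. Of 190 listed symbols, 19 were not among the counted genes and were not analysed here.

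CPM were computed from the deposited counts as own-strand counts scaled to a total of 1000000 over the miRNA genes of that library. Own-strand counts totalled 18467499 in replicate 1 and 2017294 in replicate 2. A count of 0 allowed up to 0.162 CPM and 1.49 CPM, from 3 counts of each total. Shares of counts have exact 95% Clopper-Pearson intervals. Intervals, floors and binomial p-values cover counting error only, since reads without molecular identifiers are not independent molecules. A gene was detected at 1 CPM or more in both libraries.

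With 1 group there was no contrast between groups. For 2 libraries, the smallest two-sided exact sign-flip p is 0.5, so no p across replicates was given. Fixed ratios of genes or clusters were taken within each library on the log2 scale with exact binomial intervals. A ratio was called larger than the spread when both libraries went the same way, both intervals excluded equality and the mean exceeded the SD. A bias in how well different miRNAs are read, if alike in both libraries, would show in neither the SD nor the intervals. Ratios, ranks and shares therefore compare counts, not amounts of RNA. The libraries were compared gene by gene with a two-sided exact binomial test given the library totals, with Benjamini-Hochberg adjustment at 0.05 and a fold of at least 2. That test compares 2 libraries, not conditions. Each list's median log2 ratio (CPM + 1) was placed among 10000 random lists of the same size, matched in 10 bins of mean expression. Spread over genes was summarised by edgeR's common dispersion with TMM factors, as the biological coefficient of variation (BCV). A planned chi-square test against sampling noise is not reported, since it sets the spread between separate samples against counting error alone.

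Genes were named by a rule set before the data were examined: the 20 of highest mean CPM, up to 4 detected members per list, all genes of the fixed ratios, and up to 10 past the library test with the largest log2 ratio and a mean of at least 100 counts. The 18 lists and the main tests were set then too. Alternatives were other detection limits, unstranded counts, each replicate left out, other pseudocounts (0.5 and 5), TMM and DESeq2 scaling, edgeR's exact test, and lists without abundant or multi-locus members. Alternatives chosen after seeing the data were opposite-strand counts given to the overlapping gene, and replicate 1 thinned to the depth of replicate 2.

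The tests were checked on simulated data. For replicate 1 against replicate 2 over 419 genes, Poisson counts with 200 changed genes gave 86% of 3-fold and 96% of 8-fold changes called in the right direction. Here the test was given the depths put in, while the test of the data used the observed totals. This setting replaced a first run, with means rescaled to a fixed total, in which fewer 3-fold changes were recovered. Unchanged Poisson counts gave 0 calls on average over 20 draws. These simulations hold counting error only, while the libraries had a common BCV of 17.6%. They therefore do not give the rate of false calls between separate samples. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.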

Results

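MicroRNA sequencing measured small RNAs in hearts of mouse embryos at day 11.5, when the heart tube has looped and its chambers are forming. Replicates 1 and 2 formed the only group. Own-strand counts on miRNA genes totalled 18467499 in replicate 1 and 2017294 in replicate 2, a 9.15-fold difference in depth. Values are means ± SD over n = 2 unless a replicate is named. Coordinates are on GRCm38, the build also called mm10.

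The first question was which miRNA genes make up the pool of own-strand counts. That pool leaves out multimapping reads, which were 33.8% of mapped reads in replicate 1 and 33.2% in replicate 2. It also leaves out opposite-strand reads, among them 27418 CPM where Mir378a lies, so ranks and shares hold for the counted reads only. Mir335, which lies in an intron of the imprinted gene Mest, was the most abundant at 11.2% ± 0.53 of miRNA counts (SD, n = 2). It was followed by Mir143, from the smooth muscle list, at 9.49% ± 0.34, the endothelial Mir126a at 8.21% ± 0.37, and Mir322 on chromosome X at 8.03% ± 0.22. Mir99a came next at 5.41% ± 0.20, then the cardiac Mir208b at 4.83% ± 0.26. The 10 most abundant genes together took 56.5% ± 0.41 of the counts, with 56.2% in replicate 1 and 56.8% in replicate 2. The exact 95% Clopper-Pearson intervals were 56.18 to 56.23% and 56.72 to 56.85%. Detection at 1 CPM or more in both libraries held for 419 of 1973 genes, of which 193 reached 100 CPM, 85 reached 1000 CPM and 20 reached 10000 CPM.

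The leading genes were spread over the genome. Mir335 (ENSMUSG00000065501.1) lies on chromosome 6 from 30741299 to 30741396. Mir143 (ENSMUSG00000065445.2) lies outside annotated same-strand host genes on chromosome 18, from 61649196 to 61649258. Mir126a (ENSMUSG00000065540.1), on chromosome 2 from 26591357 to 26591429, overlaps an annotated exon of Egfl7, a gene expressed by endothelial cells. Mir322 (ENSMUSG00000065418.1) lies on chromosome X from 53054255 to 53054349, and Mir99a (ENSMUSG00000065530.1) lies in an intron of Mir99ahg on chromosome 16, from 77598936 to 77599000. The rest of the 20 most abundant were Mir30e, Mir26b, Mir99b, Mir130a, Mir21a, Mir23a, Mir17, Mirlet7g, Mir652, Mir23b, Mirlet7i, Mir22, Mir351 and Mir208a, from 24974 CPM for Mir30e down to 10631 CPM for Mir208a.

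The cardiac miRNAs encoded in myosin heavy chain genes were all detected, at very different levels. Mir208b (ENSMUSG00000077928.1), in an intron of Myh7 on chromosome 14 from 54975700 to 54975776, stood at 48339 ± 2647 CPM. Mir208a (ENSMUSG00000065432.1), in an intron of Myh6 on chromosome 14 from 54949060 to 54949142, stood at 10631 ± 523 CPM. Mir499 (ENSMUSG00000076312.1), in an intron of Myh7b on chromosome 2 from 155622880 to 155622958, stood at 1795 ± 186 CPM. Mir208b exceeded Mir208a 4.55-fold, with a log2 ratio of 2.18 ± 0.01. Mir499 was 5.94-fold below Mir208a, with a log2 ratio of -2.57 ± 0.08. Both ratios, which compare counts, were larger than the spread, with exact binomial intervals excluding equality in each library.

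The cardiac and skeletal muscle list, with 8 of its 10 genes detected, took 6.08% ± 0.33 of the counts, of which Mir208b made up 79.5%. The skeletal muscle miRNA Mir206 stood at 57.1 ± 12 CPM and Mir133b at 5.20 ± 1.76 CPM. Mir1a-1 had 55 counts in replicate 1 and 3 in replicate 2, and Mir133a-1 and Mir133a-2 together had 53 and 11. These loci carry mature sequences found at more than 1 place, so their counts are uncertain and do not measure miR-1 or miR-133a, the main muscle miRNAs. The summed Mir133a loci against Mir133b gave a log2 ratio of -0.35 ± 0.16, and Mir1a against Mir133a gave -0.91 ± 1.36; neither was larger than the spread. Mir1a against Mir206 gave -4.75 ± 0.40, which was larger than the spread but has the same uncertainty. In both ratios Mir1a is Mir1a-1 alone, since Mir1a-2 is not in the count table. The strand opposite Mir1b, where Mir1a-2 lies, held 143 counts in replicate 1 and 14 in replicate 2.

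Among the other cell type lists, the smooth muscle list took 9.62% ± 0.35, of which Mir143 made up 98.7%. The endothelial list, represented by Mir126a alone, took 8.21% ± 0.37. Which cells of the heart express the listed genes was not tested, so these shares do not measure cell types. The blood cell list took 0.131% ± 0.006, the mesenchyme and epicardium list 0.527% ± 0.030, the epithelial list 0.182% ± 0.046, the liver and endoderm list 0.0763% ± 0.0230 and the neural list 0.0283% ± 0.0015. The neural share is uncertain, since 4 of its 7 detected members are multi-locus, and it was 0.0110% without them. Of the 4 detected mesenchyme and epicardium members, 2 are multi-locus, so that share is uncertain too (0.523% without them). Mir143 exceeded its neighbour Mir145a, with which it shares a locus, 76.8-fold (log2 ratio 6.26 ± 0.07). Mir126a exceeded the red cell miRNA Mir451a 98.6-fold (log2 ratio 6.62 ± 0.07). Mir451a exceeded Mir144, its partner at the same erythroid locus, 5.30-fold (2.41 ± 0.03 on the log2 scale). Mir451a exceeded the hepatocyte miRNA Mir122 3.31-fold, and here the libraries stood apart, with log2 ratios of 1.08 in replicate 1 and 2.37 in replicate 2. The blood cell share rose to 0.340% when opposite-strand counts were included, which hold the reads of the strand on which Mir142 lies.

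**Figure D1:**
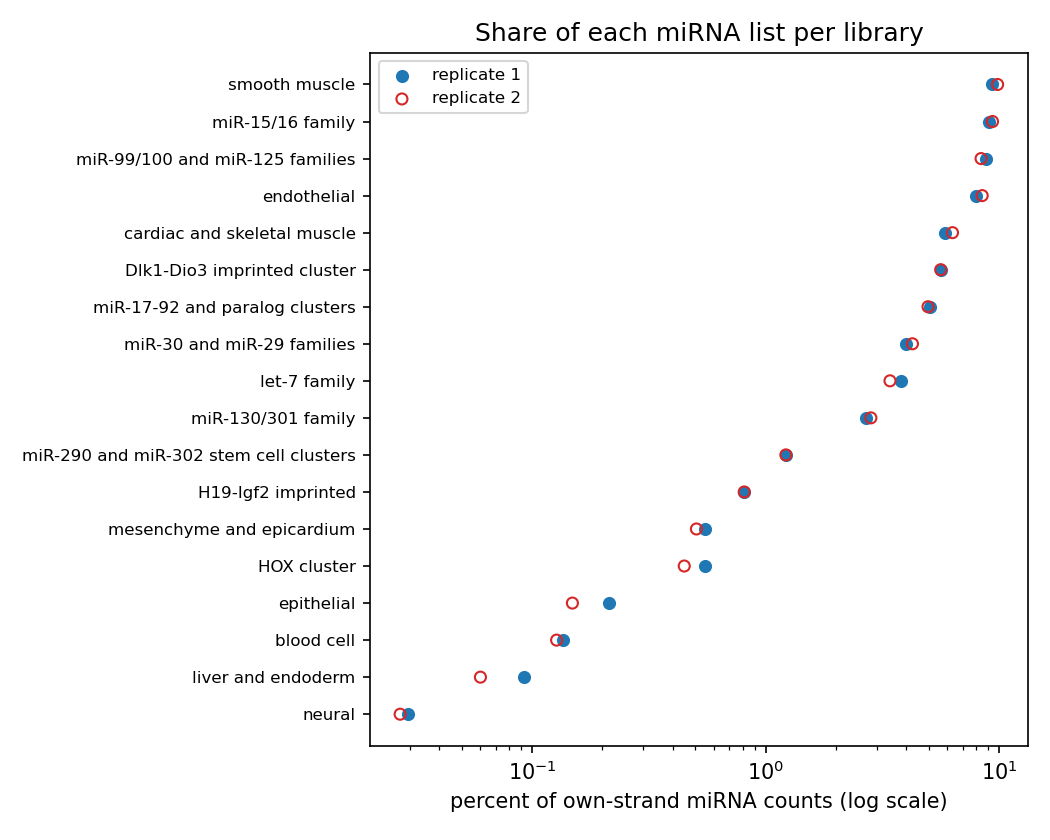
Percent of own-strand miRNA counts taken by each of the 18 lists, on a log axis, with filled points for replicate 1 and open points for replicate 2. The smooth muscle list lies near 9.62% and the neural list near 0.0283%, with the libraries furthest apart, in proportion, for the liver and endoderm list.

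Families and clusters were compared next. The miR-15/16 family took 9.20% ± 0.26, of which Mir322 made up 87.3%, and the miR-99/100 and miR-125 families took 8.60% ± 0.31. The imprinted Dlk1-Dio3 cluster on chromosome 12 had 43 detected members among 53 listed and took 5.64% ± 0.03. It was led by Mir411 at 9666 ± 383 CPM, Mir487b at 7710 ± 416 CPM and Mir431 at 5978 ± 13 CPM. Several listed members, Mir409 and Mir376a among them, are not in the count table. The cluster's share was 6.41% with opposite-strand counts given to the overlapping gene, an alternative chosen after seeing the data. The H19-Igf2 list took 0.809% ± 0.002, where Mir483 in an intron of Igf2 stood at 7845 ± 32 CPM and Mir675 in an exon of H19 at 241 ± 9 CPM. The miR-17-92 and paralog clusters took 5.02% ± 0.08, the miR-30 and miR-29 families 4.13% ± 0.17, the let-7 family 3.62% ± 0.29, the miR-130 family with its Mir301 relatives 2.76% ± 0.10 and the HOX cluster 0.50% ± 0.07. The let-7 share is uncertain, since 5 of its 10 detected members are multi-locus (3.59% without them) and 4 listed members, Mirlet7e and Mirlet7f-1 among them, are not in the count table. Multi-locus members also number 4 of 15 detected for miR-17-92 and paralogs, 3 of 9 for miR-30 and miR-29, 2 of 7 for miR-15/16, 2 of 6 for miR-99/100 and miR-125 and 1 of 5 for the HOX cluster.

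The miR-17-92 locus, which is active in proliferating cells, exceeded the miR-106b-25 locus 3.03-fold (log2 ratio 1.60 ± 0.04) and the miR-106a-363 locus 61.0-fold (5.93 ± 0.04). The pluripotency-associated miR-290 and miR-302 clusters together took 1.22% ± 0.004. Within them the miR-302 cluster exceeded the miR-290 cluster 18.2-fold (4.19 ± 0.09), with Mir302a at 4037 ± 75 CPM and Mir294 at 259 ± 20 CPM. The Mir199 loci summed were 13.3-fold below Mir214 (-3.73 ± 0.11). Of them, Mir199a-2 lies with Mir214 in Dnm3os on chromosome 1, while Mir199b on chromosome 2, with 5936 counts in replicate 1, held most of the sum. Mir199a-1 and Mir199a-2 are uncertain for the reason given for Mir1a-1. Multi-locus genes were marked by symbol alone, which cannot show whether Mir199b shares a mature sequence with them. The ratio to Mir214 is therefore uncertain as a whole. Of the 13 fixed ratios, 11 were larger than the spread.

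The libraries were then compared with each other. The most abundant genes differed little: Mir335 was 0.935-fold in replicate 2 relative to replicate 1, and Mir143 was 1.05-fold. Mir122, a liver miRNA in an annotated exon of AC157910.3, was lower in replicate 2, at 160 CPM against 395 CPM in replicate 1, a ratio of 0.405 with an exact interval of 0.361 to 0.453 (exact binomial test, adjusted p = 2.28e-73). Mir375, an endocrine and gut miRNA, was lower as well, at 48.6 against 112 CPM, a ratio of 0.432 (exact binomial, adjusted p = 4.78e-19). The largest ratio was that of Gm26117, at 345 CPM in replicate 1 and 18.3 CPM in replicate 2.

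Between the libraries 11 genes passed an adjusted p of 0.05 and 2-fold, with 8 lower and 3 higher in replicate 2. Besides Mir122, Mir375 and Gm26117, Mir6240, Mir6538, Mir5126, Gm24245 and Mir219a-1 were lower, and Mir6236, Mir7082 and Mir133a-1 were higher. The p-values allow for counting error alone, not for the spread between hearts. Mir7082, Mir133a-1 and Gm24245 rest on 10, 11 and 11 counts in replicate 2, and Mir219a-1 and Mir133a-1 are multi-locus. Mir7082 is outside the naming rule and was named after its values were seen. edgeR's exact test at the common dispersion called 5 genes, since it also allows for the spread over genes; that dispersion already holds the difference between these libraries.

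**Figure D2:**
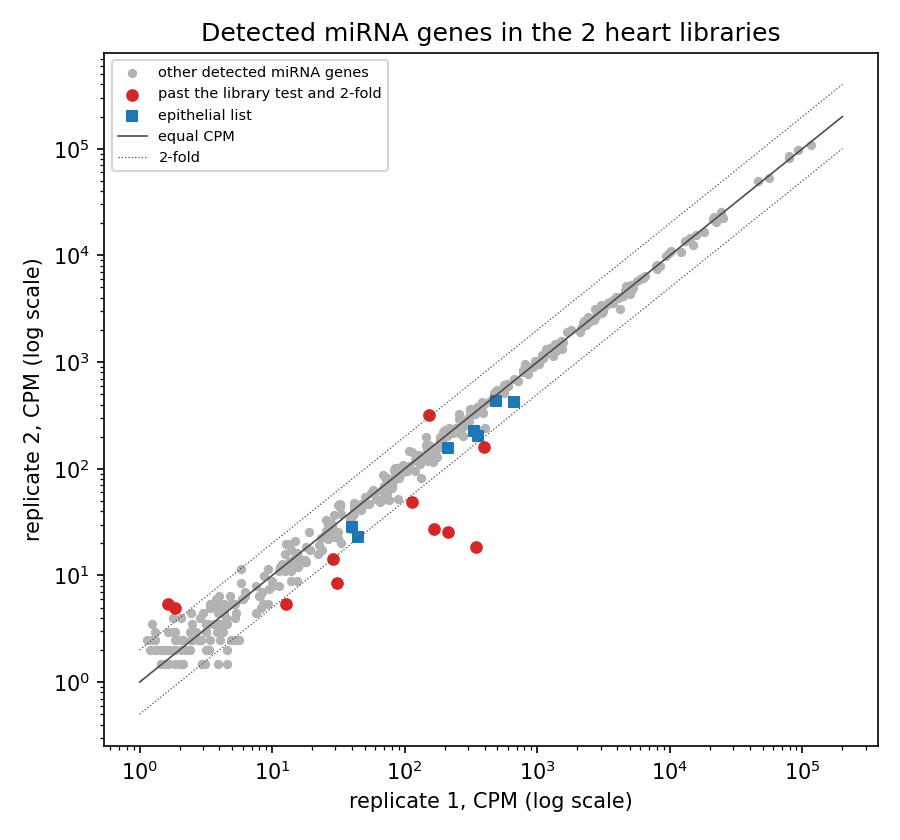
CPM of the 419 detected miRNA genes in replicate 1 (horizontal) and replicate 2 (vertical), on log axes, with the 11 genes past the library test in red, the epithelial list as blue squares, a solid line for equal CPM and dotted lines for 2-fold. Most genes lie near the line of equal CPM, and the 7 epithelial genes lie below it.

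Pearson's r across the 419 detected genes was 0.993 and Spearman's rho was 0.988, on log2(CPM + 1). Genes are not independent replicates, so no p is given. The common BCV was 17.6%, and the median absolute fold between the libraries was 1.11. The libraries were counted as separate samples because the labels give them as biological replicates.

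By median log2 ratio the epithelial list stood furthest apart; by share of counts it was the liver and endoderm list, at 0.0926% in replicate 1 and 0.0601% in replicate 2. All 7 epithelial members, the miR-200 family with Mir203 and Mir205, were lower in replicate 2 at an adjusted p under the threshold (exact binomial), though none by 2-fold. Without a fold minimum, 123 of the 419 detected genes passed this test, 60 higher and 63 lower in replicate 2. Abundant genes passed at ratios near equality, such as Mir143 at 1.05, so passing alone does not set a list apart. Mir429 stood at 668 and 418 CPM, Mir200c at 358 and 204 CPM, Mir205 at 332 and 226 CPM and Mir203 at 487 and 431 CPM in replicates 1 and 2. The list's median log2 ratio was -0.55, at percentile 0 of 10000 matched random lists. Mir200a, Mir200b and Mir429 share 1 locus and Mir141 and Mir200c another, so the members are not independent.

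The let-7 family had a median log2 ratio of -0.16 (percentile 1.86), with 5 of its 10 detected members lower by the test, 0 higher and 5 not past it; 5 of the 10 are multi-locus, so this median is uncertain too. The miR-30 and miR-29 families had a median of 0.09 (percentile 97.4), with 5 of 9 members higher. The smooth muscle list had a median of 0.12 (percentile 96.9), with Mir143 and Mir145a both higher. The other 14 lists lay within the central 90% of random lists. In the liver and endoderm list Mir122, Mir375 and Mir192 were lower and 5 members did not pass, among them Mir215 at 261 and 243 CPM. In the HOX cluster Mir10a stood at 4226 CPM in replicate 1 and 3123 CPM in replicate 2, a ratio of 0.739, and Mir196b was higher in replicate 2, with a ratio of 1.14; the other 3 detected members did not pass. With 18 lists and 1 library on each side, these percentiles describe these libraries only.

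**Figure D3:**
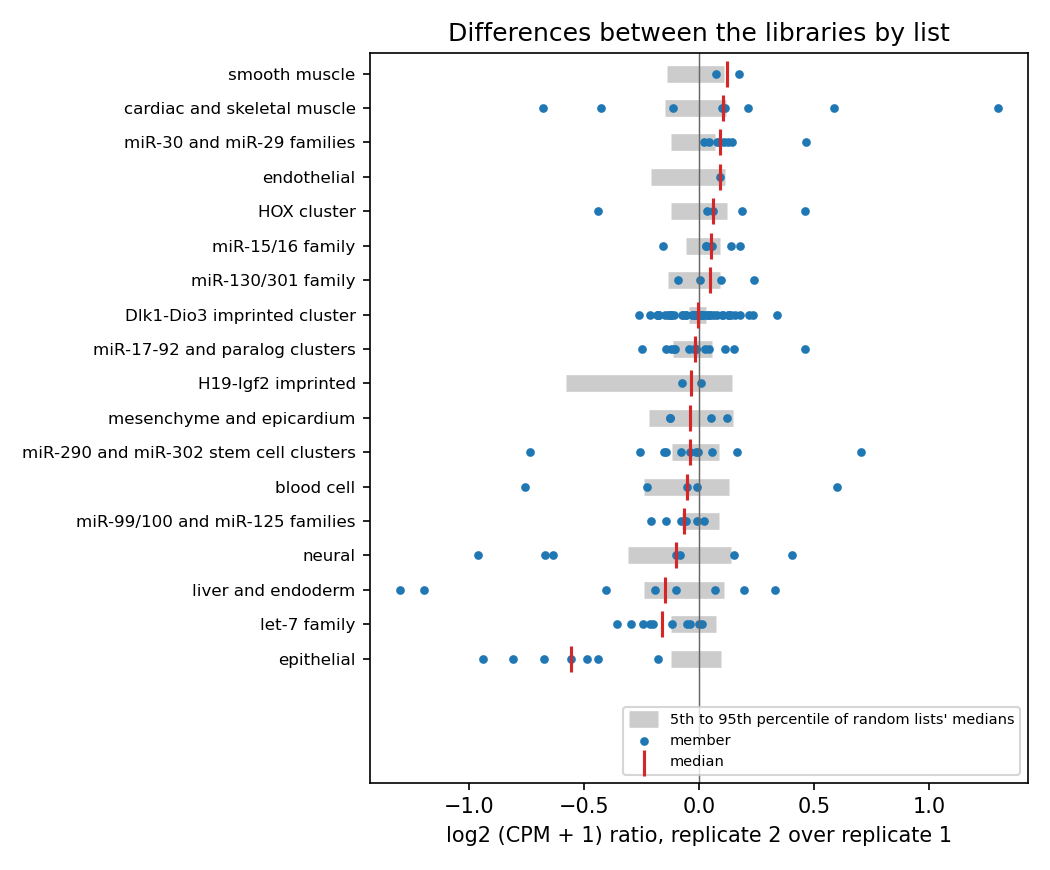
Log2 ratio of CPM + 1, replicate 2 over replicate 1, for each detected list member (blue points), with the list's median in red and a grey bar from the 5th to the 95th percentile of medians of matched random lists. The epithelial median of -0.55 lies left of its bar.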

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

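Reads in the column taken as the strand opposite to the counted genes were not used in the comparisons, and they stood above the limit that a count of 0 allows. They made up 4.59% of gene counts in replicate 1 and 4.48% in replicate 2. Gene models with at least 1000 such counts in both libraries numbered 9, and each lies opposite an M21 miRNA gene that has no row of its own in the count table. The opposite strand of Gm25301, where Mir378a lies, held 27418 CPM, which would rank among the 10 most abundant genes. The opposite strand of Gm24321 (Mir409) held 4460 CPM, that of Gm25927 (Mirlet7e) 4444 CPM and that of Gm25252 (Mir376a) 2944 CPM. That of Mir299b (Mir299a) held 2266 CPM, that of Mir142b (Mir142) 2245 CPM and that of Gm24083 (Mir191) 1919 CPM. That of Gm25750 (Mir380) held 1055 CPM and that of Mir497b (Mir497) 654 CPM.

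The paragraphs that follow weigh 3 patterns. The tests chosen after the result was seen are the cluster comparison restricted to detected partners, the thinning of the epithelial list and the thinning over all detected genes. When the planned cluster, hairpin, list and thinning tests were taken to decide was also revised after their values were seen. With 1 group in the design, no biological explanation was tested.

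Many multi-locus miRNA genes had few counts, though not all: Mir92-1 stood at 2974 CPM and Mir16-1 at 2005 CPM. The explanation weighed was that reads mapping to several loci were not counted. The comparison set beforehand, of 53 multi-locus loci with single-locus partners within 10 kb, gave a median log2 difference of -0.44, inside the 2-fold bound that was set as evidence against the explanation. That comparison cannot decide, because 31 of the 53 loci lie in a repeat cluster whose partners were themselves at 0.352 CPM, leaving no room below them. A restriction made after that value was seen left the 22 loci with partners at 1 CPM or more. Their median was -4.90 (95% bootstrap interval -6.53 to -2.67), and 21 lay below their partners. Mir26a-2 lay above its partner (log2 difference 3.69), and Mir16-1 (-0.84), Mir92-2 (-0.78) and Mir194-2 (-0.40) lay less than 2-fold below. Uncounted multimapping reads would give a low median, but this comparison cannot decide either. The minimum was set on the partners alone, and single-locus genes were not compared with their neighbours in the same way. Such neighbours can also stand far apart, as Mir143 stood 76.8-fold above Mir145a. Some of the 22 loci share partners, so they are not independent. The 258 hairpins whose every 20-mer recurs in another hairpin held 0.0304% of counts, but unexpressed hairpins would show the same, and 671 hairpins with some shared 20-mers held 8.50% in replicate 1 and 8.67% in replicate 2.

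Marker miRNAs of other tissues differed between the libraries. Tissue carried over in the dissection was set to predict that all members of a list move one way by a like fold, and members going both ways or a median within the central 90% of random lists was set as evidence against it. The neural list (percentile 54.3), the blood cell list (42.5) and the liver and endoderm list (18.3) met that bound. The last stood at 1.19 with unstranded counts. The bound was set wrongly. By direction alone the members of these lists went both ways, and a median over such members cannot decide. Expression in the heart itself would hide a small share of other tissue in some of them. Members past the test were 2 lower and 0 higher in the neural list, 3 and 0 in the liver and endoderm list, and 2 and 1 in the blood cell list. Carry-over stays open for these 3 lists. All 7 epithelial members were lower in replicate 2 (percentile 0), and a move 1 way is what carry-over was set to predict. Each lay within 2-fold of the list's median of -0.55, but an unchanged member would too, so a like fold was not shown. Their ratios ran from 0.512 (Mir141, interval 0.372 to 0.689) to 0.885 (Mir203, 0.825 to 0.949). The members come from few loci, and heart cells might express some of them. Epithelial carry-over and a difference between the hearts themselves both stay open, untested.

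Genes differed between the libraries, which also differ in depth. The thinning test set beforehand, on 193 genes at 100 CPM or more in both, found 2 past 2-fold at full depth and a median of 2 (range 1 to 2) over 100 draws, but cannot decide, because that minimum leaves out 9 of the 11 genes that differed, Gm26117 among them. Over all detected genes, at least 1 gene passed the library test in 100 of 100 thinnings (median 9, range 6 to 12), and the epithelial list stayed below the 5th percentile in 100 of 100. Neither outcome can weigh depth as a cause. Thinning keeps the expected ratios and the library test already allows for the totals, so both followed from counts already seen. They show only that these differences remained at the depth of replicate 2. Thinning cannot undo differences made before sequencing, and what set the libraries apart was not tested.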

How the results depend on the processing

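Across 55 results and 274 alternative values, no called value changed sign. Values that were not called did so for Mir1a over Mir133a (0.05 without replicate 2) and for the Dlk1-Dio3 list (0.01 with TMM). The 13 ratios kept their side of the threshold under all 42 alternatives. For the called ratios this was fixed in advance wherever a replicate was left out, since each library's interval already excluded equality. The count of detected genes stayed within 1.5 times (299 to 587). No paired analysis was possible because there is 1 group. The share of named genes of other kinds could not be computed, since all matched genes are miRNA genes. Leaving out either replicate moved no value beyond the spread, which follows from n = 2. With unstranded counts, the share of the 10 most abundant genes was 54.4%, the blood cell share was 0.340%, and the median log2 ratios of the muscle list (0.11) and the liver and endoderm list (-0.25) left the central 90% of random lists; the muscle list did so too at a pseudocount of 5 (0.11). Giving opposite-strand counts to the overlapping gene, an alternative chosen after seeing the data, also put the blood cell share at 0.340%. Leaving out the most abundant gene gave shares of 6.85% for muscle and 0.148% for blood, and leaving out the 5 most abundant gave 10.5% for muscle, 0.228% for blood, 0.132% for liver and endoderm and 0.315% for epithelial, by the smaller total. Lists that lost members that way fell, smooth muscle to 0.215%, endothelial to 0, the miR-15/16 family to 2.02% and the miR-99/100 and miR-125 families to 5.53%. The neural share was 0.0110% without multi-locus members. Over all 18 lists, 57 of 126 alternative shares moved by more than 1 SD. Pearson's r was 0.991 at 10 CPM, and Spearman's rho was 0.943 with no filter. Genes that differed between the libraries numbered 7 at 10 CPM, 123 with no fold minimum and 5 by edgeR's exact test, against 11; thinning replicate 1, chosen after seeing the data, gave 9. Other causes were not tested. Replicate 2 limits the depth, at 1.49 CPM for a count of 0.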

Other observations

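The groupings here were chosen after the values were seen. They use own-strand counts, which leave out Dlk1-Dio3 genes that are not in the count table, such as Mir409. Imprinted loci (Mir335 at Mest, the Dlk1-Dio3 cluster, Mir483 at Igf2, Mir675 at H19, and Mir296 with Mir298) took 18.8% ± 0.59 of miRNA counts (SD, n = 2). Chromosome X held 12.7% ± 0.12, most of it from the neighbouring Mir322, Mir503 and Mir351, which together took 9.49% ± 0.15. Chromosome 12, which carries the Dlk1-Dio3 cluster, had 56 detected genes, the most of any chromosome, and 6.07% ± 0.05 of the counts.

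The miR-302 cluster, known from pluripotent cells, took 1.16% of counts in both replicates. The miR-200 family took 0.132% in replicate 1 and 0.0831% in replicate 2, a 1.59-fold difference.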
